A study of Homo sapiens with 4 samples.

How the data were processed

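Chromatin immunoprecipitation with a pan-Argonaute antibody (AGO, the protein family that carries small RNAs) was read on promoter tiling arrays in WI-38 cells, a human diploid fibroblast strain grown at 3% oxygen per the labels' protocols. The 4 two-colour arrays cover 2 states, pre-senescent cells and cells made senescent with a retrovirus that carries RASV12, an activated RAS oncogene. Each state has 1 array for each of the 2 parts of the promoter design, here called part 1 (1of2) and part 2 (2of2). The parts carry different promoters, so there is 1 array per state and part and no replicate. Samples were grouped by title. On the senescent arrays the source name of the ChIP channel reads pre-senescent, while the title, cell type and treatment of the same channel read senescent. The labelling protocol says that the DNA of both channels came from cells immunoprecipitated with rabbit IgG. The antibody field says pan-AGO for the ChIP channel and none for input. These label conflicts could not be settled from the values.

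Cy5 carried ChIP DNA and Cy3 carried input DNA, per the labels' protocols. The ChIP is called AGO here after the titles and the antibody field. The scanner intensity of each spot was extracted with NimbleScan 2.3.78 on an HG18 promoter design, per the file headers. What was done to the background is not given in the sources used here. The deposited value tables hold log2 ratios, which equalled log2 of Cy5 over Cy3 intensity plus 1 constant per array, with a slope of 1.0 and a largest residual of 0.005. That constant equalled minus the Tukey biweight mean of the array's log2 ratios. The medians of the deposited log2 columns were −0.02 and 0.0 for pre-senescent parts 1 and 2, and 0.05 and 0.04 for senescent parts 1 and 2.

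For the main values, log2(Cy5/Cy3) of the scanner intensities was centred on the median of the tiled probes of each array, with no loess, quantile or background step. Random-sequence control probes were left out of the ratios and used as background. Means were taken over windows of 5 consecutive probes within a tiled region, close to the 500 bp to which chromatin was sheared per the labels' protocols. A region was counted as enriched with a window at or above 1. A gained region had a window at or above 1 in senescent cells and at least 1 above the same window in pre-senescent cells, and a lost region the reverse. Mirror counts applied the same rule to the negative side. Counts were repeated after shuffling the probe ratios of each array 20 times. With no replicates, no test between states was run and no p-value is given. SDs are over the 5 probes of a window and SEs are over regions of 1 array, and neither covers the spread between cultures. For these arrays, their number limits the precision.

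The window counts were tested on simulated data, made by shuffling the probe ratios of the real arrays and planting a lift in 200 regions. Shuffling removed the correlation of neighbouring probes, which was 0.48 to 0.53 at 100 bp, so the rates hold for data without it. A lift of 1.5 on the log2 scale was called gained in 87.5% of planted regions on part 1 and 98.0% on part 2, while 30.2% and 48.2% of the regions without a planted lift were also called gained. The threshold of 1 is therefore permissive, and counts at 2 are given beside it. The threshold of 2 was added after seeing the data.

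Regions are named by their HG18 coordinates as the files give them. The gene table at hand is for GRCh38.p14, so it was not used here, and no coordinates were converted. For this reason the 23 gene lists fixed beforehand, the genes chosen by name, the profile around start sites and the check of HRAS input were not run. The named regions followed a rule fixed before the data were examined. It took, outside chromosomes X and Y and with at least 8 probes, the 12 gained and the 12 lost regions with the largest window difference whose odd and even probes, in a window widened to 10 probes, both moved the same way, and the 8 regions with the highest window in each state. The part of the rule that asked for exactly 1 gene per region could not be applied. The profile was instead taken over distance from the ends of tiled regions, a choice made after seeing the data.

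Alternatives were Tukey biweight centring, within-array loess on intensity (limma 3.58.1, span 0.3), normexp with an offset of 50, scaling to 1 SD, the deposited log2 table, windows of 3 and 7 probes, thresholds of 0.75 and 1.5, leaving out the 10% of probes with the dimmest input, and window medians. Alternatives added later were a threshold of 2, windows within 600 bp, windows with ChIP intensity above the 95th percentile of the random-sequence probes, autosomes only, a matching difference in the ChIP channel alone, and named differences with the dimmer ChIP raised to that percentile, with and without loess. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.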

Results

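The series asked where AGO proteins sit on promoters in pre-senescent WI-38 fibroblasts and in the same strain made senescent by RASV12. The arrays tiled 23047 promoter regions with 757904 probes, 11417 regions on part 1 (chromosomes 1 to 9 and part of 10) and 11630 on part 2 (the remaining chromosomes). Regions held a median of 32 probes at a median spacing of 100 bp. There was 1 array per state and part, so no difference below has a replicate check. In pre-senescent cells the median ChIP intensity of tiled probes was 2.76 times that of random-sequence probes on part 1 and 2.74 times on part 2. In senescent cells it was 1.47 times and 1.94 times.

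The first comparison asked which promoters carried AGO signal in each state. In pre-senescent cells the highest window lay on chromosome 22 at 19418205 to 19424691, with a log2 ratio of 3.76 ± 0.70 (SD over 5 probes), and read 0.74 ± 1.47 in senescent cells. The next regions were on chromosome 5 at 95210447 to 95214697 with 3.38 ± 1.84 and on chromosome 6 at 29378945 to 29383195 with 3.35 ± 0.72. This order is that of median centring. In the same windows normexp read 3.73 on chromosome 6 and 3.70 on chromosome 22. Pre-senescent input in the chromosome 6 window averaged 835, below the tiled median of 1170 on that array. Only 42.0% of tiled probes on that array had input above the 95th percentile of the random-sequence probes. The mean input of this window was therefore not above that level. Loess read 3.53 on chromosome 22, 2.92 on chromosome 6 and 2.85 on chromosome 5. In senescent cells the highest window lay on chromosome 1 at 89510369 to 89514619, with 4.64 ± 0.81, where pre-senescent ChIP was not above the 95th percentile of the random-sequence probes. It was followed by chromosome 13 at 99421429 to 99425679 with 4.51 ± 0.28 and chromosome 15 at 39005338 to 39009772 with 4.47 ± 1.08. After loess the window on chromosome 1 was still the highest of the 8 named ones, at 3.79. Chromosome 2 at 178125000 to 178129254, with 3.48, then lay above chromosome 13 with 2.97 and chromosome 15 with 2.88. Of the 8 named regions of pre-senescent cells, 2 were also at or above 1 in senescent cells, and of the 8 of senescent cells none reached 1 in the same window of pre-senescent cells.

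At a threshold of 1, 8585 regions were enriched in pre-senescent cells, against 6591 mirror regions. In senescent cells 13423 regions were enriched, against 6853 mirror regions. Shuffling the probes gave a mean of 3542.8 enriched regions in pre-senescent cells and 11168.1 in senescent cells, with the order of probes removed. The shuffled mirror means were 1948.5 and 2913.1. Senescent part 2 had shuffled means of 6644.4 enriched and 234.6 mirror regions, and senescent part 1 had 4523.6 and 2678.4. An excess of enriched over mirror regions at 1 was thus present without the order of probes. At a threshold of 2, 758 pre-senescent and 4594 senescent regions were enriched, against 417 and 319 mirror regions. The shuffled means of enriched regions at 2 were 8.8 and 336.5.

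The parts did not behave alike. At 1, senescent part 2 had 7454 enriched and 1466 mirror regions, while senescent part 1 had 5969 and 5387. Pre-senescent part 1 had 5323 enriched and 3323 mirror regions, and pre-senescent part 2 had 3262 and 3268. The excess over mirror regions depended on the normalization. Mirror regions outnumbered enriched ones in pre-senescent cells after loess, 8369 to 5410, and after normexp, 11068 to 9178. After loess at a threshold of 2, senescent part 1 had 693 enriched and 399 mirror regions. Senescent part 2 had 234 and 280, or 0.836 enriched regions per mirror region. Pre-senescent part 1 had 128 enriched and 577 mirror regions at that setting, and pre-senescent part 2 had 94 and 381.

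**Figure D1:**
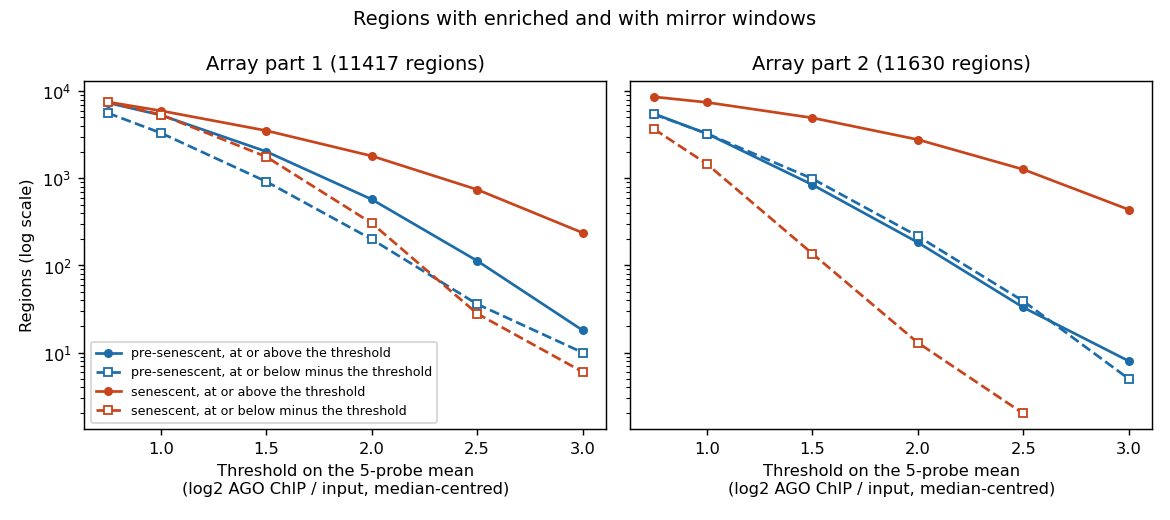
Number of tiled regions (log axis) with a 5-probe window at or above the threshold (solid lines) or at or below its negative (dashed lines), by threshold on the median-centred log2 ratio, for pre-senescent (blue) and senescent (orange) arrays of each part. On part 2 the senescent lines part most, with 2787 regions above 2 and 13 below −2, and the senescent mirror count of 0 at 3 is not drawn.

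The second comparison asked which promoters gained or lost AGO signal in senescent cells. Many of these windows held probes of the dimmer state that were not above the 95th percentile of the random-sequence probes, in 11 of the 12 named gained and 11 of the 12 named lost regions. The lower bounds given here raise such probes to that level, under median centring and again under loess. They are bounds on the ratio for that ChIP floor only, and differences in input or hybridisation between the arrays remain in them. On chromosome 13 at 44458186 to 44465071 the window read −2.13 ± 1.32 in pre-senescent and 4.19 ± 0.83 in senescent cells, a log2 difference of at least 5.81, and at least 4.54 after loess. Input intensity there also differed, with 9298 in pre-senescent and 2725 in senescent cells. On chromosome 3 at 187980559 to 187984828 the log2 difference was at least 6.13, and at least 5.50 after loess. Both channels moved there, with input intensities of 24354 and 4630 and ChIP intensities of 3498 and 31896 in pre-senescent and senescent cells. On chromosome 12 at 46499174 to 46503424 it was at least 5.16, and at least 3.75 after loess. On chromosome 2 at 32353034 to 32357284 it was at least 4.66, and at least 4.31 after loess. The 12 named gained regions lay 6 on each part, and in 7 of them the mean pre-senescent ChIP of the window was not above the random-sequence level. Among losses, the window on chromosome 7 at 43761296 to 43765553 read 2.54 ± 0.68 in pre-senescent and −2.46 ± 0.32 in senescent cells, lower by at least 4.48 on the log2 scale, and by at least 3.77 after loess. The senescent ratio was lower by at least 4.79 on chromosome 6 at 32264943 to 32274778 and by at least 4.56 on chromosome 1 at 158181260 to 158185510. On chromosome 7 at 95616598 to 95620854 it was lower by at least 4.08. After loess these 3 bounds were 4.46, 4.75 and 2.92. Of the 12 named lost regions, 11 were on part 1, and in 6 the mean senescent ChIP of the window was not above the random-sequence level. The 24 regions were chosen for their size of difference, and before any bound the sizes of 11 of them moved under loess by more than the spread between their probes. The bounds after loess ran from 3.45 to 5.50 in gained and from 2.28 to 5.93 in lost regions. The bound of 5.93, on chromosome 19 at 61051698 to 61061374, came with input intensities of 8477 in pre-senescent and 29693 in senescent cells.

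**Figure D2:**
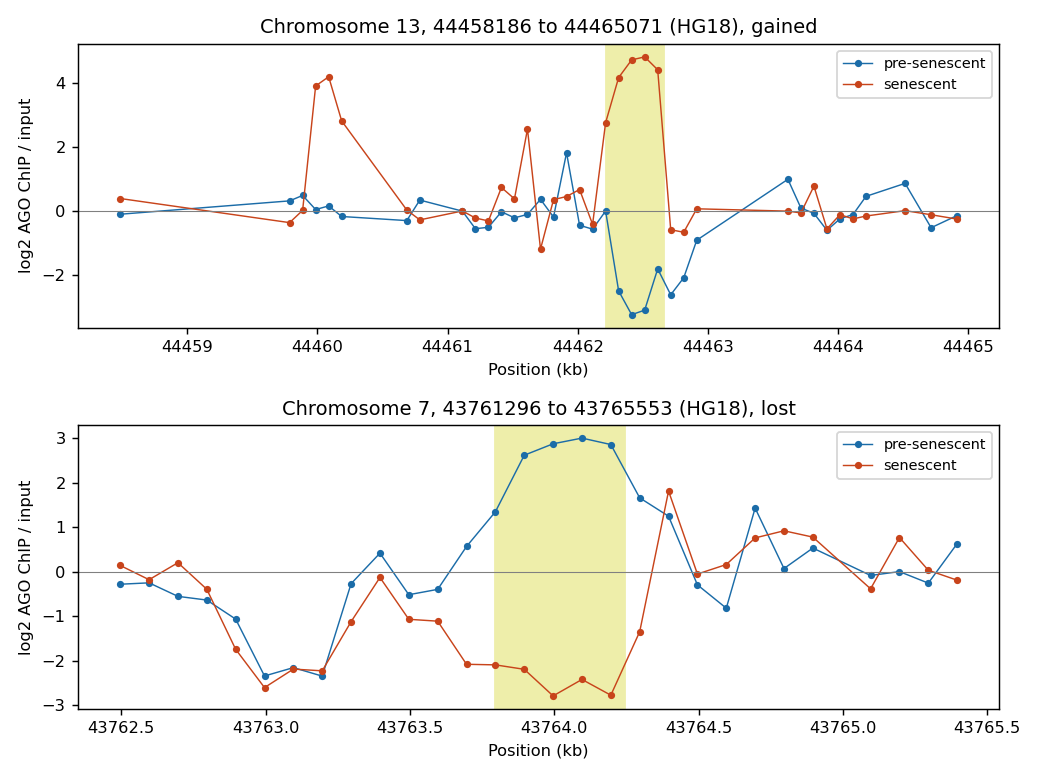
Median-centred log2 ratio of AGO ChIP to input for each probe (points) against HG18 position in kb, in pre-senescent (blue) and senescent (orange) cells, for the first gained and the first lost region, with the 5-probe window shaded. In both shaded windows the dimmer ChIP was not above the 95th percentile of the random-sequence probes, so the differences are given as lower bounds for that floor. Under median centring they are 5.81 in the gained and 4.48 in the lost region, and after loess 4.54 and 3.77.

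Over all regions, 11586 gained and 6675 lost a window, against mirror counts of 4451 and 3730. At a threshold of 2, 3503 gained and 575 lost. Part 1 gave 4827 gained regions against 3819 mirror regions and 4353 lost regions against 1547. Part 2 gave 6759 gained against 632 and 2322 lost against 2183, and at a threshold of 2 its 116 lost regions did not exceed 118 mirror regions. After loess, lost regions over both parts were fewer than their mirror, 4203 against 5452. In gained regions the median window difference was 1.85 on part 1 and 2.00 on part 2, and the median difference of the ChIP channel alone was 2.16 and 1.76. Each channel was centred on its own median there, so the channels do not add up to the ratio. With the parts pooled, gained regions outnumbered lost ones under each alternative, by 1.37 to 6.09 times. Most of this came from part 2. At thresholds of 0.75, 1 and 2 there were 1.03, 1.11 and 2.72 gained regions per lost region on part 1, and 1.97, 2.91 and 19.4 on part 2. In shuffled data, 30.2% of regions without a planted lift on part 1 and 48.2% on part 2 were called gained at 1. The shares of real regions called gained were 42.3% and 58.1%. The counts therefore do not give a number of bound promoters.

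The next comparison set the enriched promoters of the 2 states against each other. At 1, 3206 regions of part 1 were enriched in both, against 2783.0 for independent lists, a ratio of 1.152, and 2369 of part 2, against 2090.7, a ratio of 1.133. At 2, 123 regions of part 1 were shared against 90.8, a ratio of 1.354, and 71 of part 2 against 44.1, a ratio of 1.61. With the parts pooled the ratio at 1 was 1.115, below that of either part because the parts differed in their enriched shares. Among the top 5% of regions of each state, 84 were shared against 57.7. Regions held 5 to 453 probes, and those with more probes have more windows that can reach a threshold in either state. The numbers for independent lists do not allow for this, nor do the correlations of highest windows given below. Across regions, which are not independent replicates, region means of the 2 states correlated with r = 0.049 (Spearman's rho 0.040) on part 1 and r = 0.174 (rho 0.188) on part 2. On part 1 the sign turned to −0.0284 with region medians. The highest windows of the regions correlated with r = 0.173 (rho 0.189) on part 1 and r = 0.209 (rho 0.223) on part 2. Within each array, odd and even probes of a region correlated at 0.779 and 0.727 in pre-senescent and 0.786 and 0.808 in senescent cells. Over single probes, input intensities of the states correlated with rho 0.885 and 0.891, and ChIP intensities with rho 0.722 and 0.736. The log2 ratios of single probes correlated with r = 0.086 on part 1 and 0.099 on part 2.

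**Figure D3:**
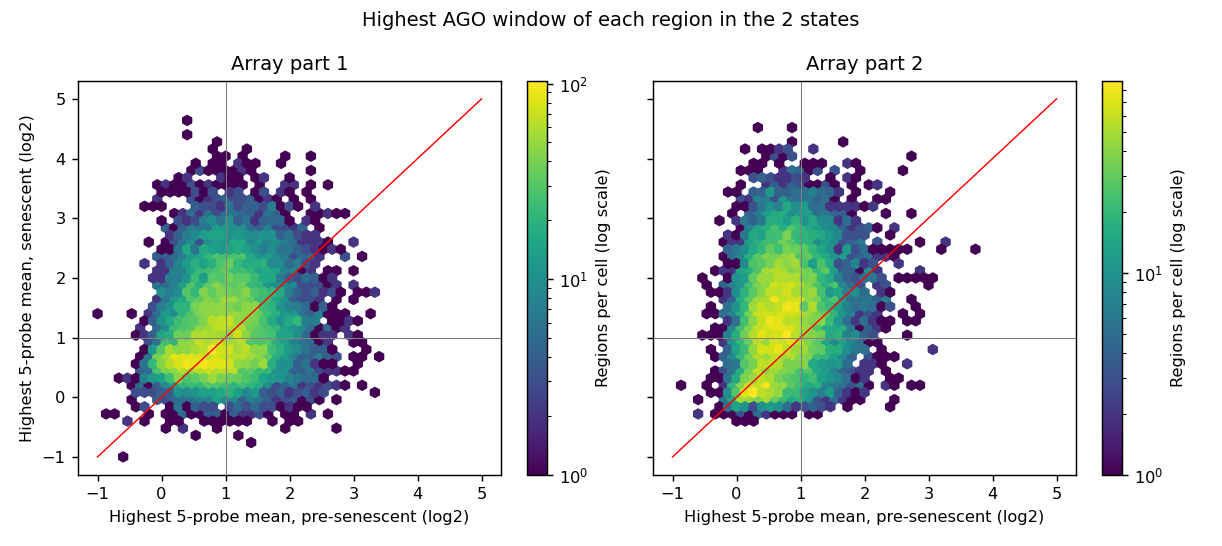
Highest 5-probe log2 ratio of each region in senescent (y axis) against pre-senescent cells (x axis), for each part, with colour for the number of regions per cell on a log scale, grey lines at 1 and a red line of equality. On part 2 most regions with a senescent window above 1 lie left of the pre-senescent line, where 5085 regions were enriched in senescent cells only. Only 28.0% of part 2 regions were enriched in pre-senescent cells, so most would lie there for independent lists as well.

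Within tiled regions, the mean ratio of AGO ChIP to input in senescent cells was higher on both flanks, 400 to 1000 bp from the ends, than at the centre. Nearer the ends it was not higher on part 1, with −0.021 at 0 to 200 bp and −0.017 at 4000 to 4200 bp. In regions of 4250 bp, probes 400 to 1000 bp from the nearest end exceeded those at least 1400 bp from it by 0.057 ± 0.010 (SE over 4949 regions) on part 1 and 0.153 ± 0.010 (4878 regions) on part 2. In pre-senescent cells the contrast was 0.028 ± 0.0085 and −0.013 ± 0.0078. It was positive in 51.9% of regions on part 1 and 58.3% on part 2 in senescent cells, and in 51.6% and 49.6% in pre-senescent cells. The distances of 400 to 1000 bp and 1400 bp were chosen after seeing the profile. After loess the senescent contrast was 0.0771 on part 1 and 0.0663 on part 2, and the pre-senescent contrast was −0.0336 and −0.0433, a turn of sign on part 1. The ChIP channel alone had a contrast of 0.286 in pre-senescent and 0.264 in senescent cells on part 1, and 0.258 and 0.323 on part 2. The input channel had 0.258 and 0.207 on part 1, and 0.271 and 0.170 on part 2, so the ratio contrast of the states differed through input on part 1 and through both channels on part 2. The highest window of enriched senescent regions lay in the flanks in 40.2% of cases, against 32.9% of all windows and 30.6% in pre-senescent cells. At a threshold of 2 the shares were 40.4% in senescent and 35.3% in pre-senescent cells.

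**Figure D4:**
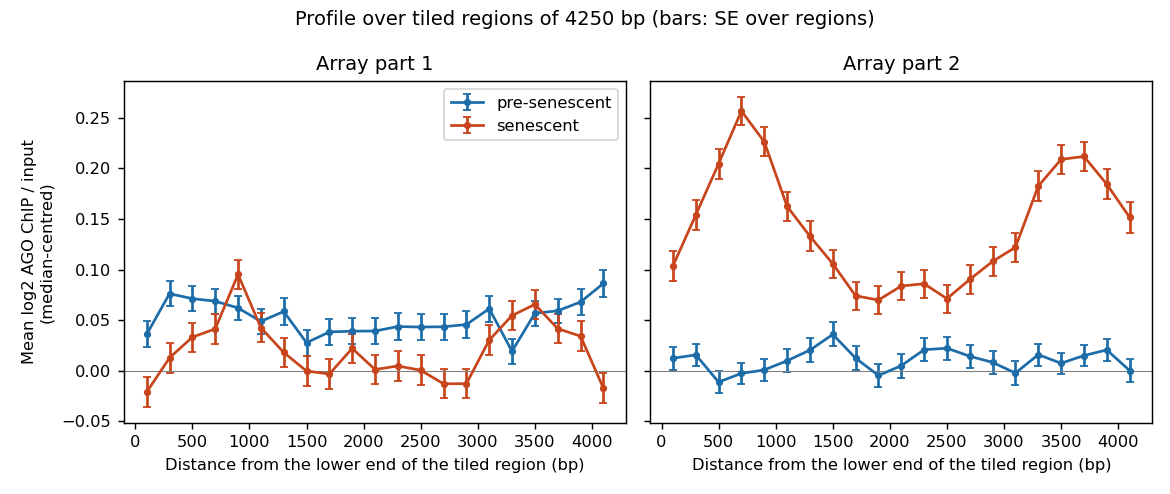
Mean log2 ratio of AGO ChIP to input in bins of 200 bp along tiled regions of 4250 bp, in pre-senescent (blue) and senescent (orange) cells, for each part, with bars for the SE over regions. Senescent part 2 shows 2 peaks, the higher of 0.257 at 600 to 800 bp from the lower end.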

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

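The tests at a threshold of 2, with their bounds, and the test on input intensity were chosen only after the counts at several settings had been seen. The rules on which array decides, which tests of the excess, the flank contrast and the correlation were void, and the margin of 2 SE around the bounds of the senescent excess were also set after counts or results had been seen, the margin after the loess value was known. The other tests were written before their results were seen.

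The excess of enriched over mirror regions in senescent cells was weighed first. At 1 it was also present after shuffling, with means of 11168.1 enriched and 2913.1 mirror regions, so it did not need runs of neighbouring probes. With arrays scaled to 1 SD the lower of the 2 arrays had 1.29 enriched regions per mirror region at 1 and 16.9 at 2, which decides nothing about a wider spread, since 1 factor per array only moves the threshold. Probes with dim input did not account for the excess at 2, as 5.59 regions per mirror region were left without them. Dye bias that varies with intensity stays open on both parts. After loess the ratio of senescent part 2 fell from 5.08 to 1.202 ± 0.023 (SE over regions) at 1, too near the bound to decide. At 2 it fell to 0.836, under the bound of 2 chosen there, and the excess ended. The fall cannot tell dye bias from binding, since ChIP is part of the intensity on which loess fits. Loess also left pre-senescent parts 1 and 2 with 0.222 and 0.247 enriched regions per mirror region at 2. On part 1 the ratio at 1 rose after loess from 1.108 to 1.663. That decides nothing, because 1.108 was already under the preset bound. At 2 the part 1 ratio fell from 5.91 to 1.74, under the bound of 2 chosen there, though enriched regions still outnumbered mirror regions. Keeping only windows with ChIP above the random-sequence probes gave 2.40 but decides nothing, because that filter removed 71.1% of mirror and 0.777% of enriched windows; a change of AGO binding in senescence also stays open and was not tested.

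The higher senescent signal 400 to 1000 bp from the region ends was weighed next. After loess the lower of the 2 parts kept a contrast of 0.0663, above the preset bound of 0.03 by more than 2 SE, so dye bias that varies with intensity does not account for the whole senescent contrast. Brighter input at the same place stays open. Within deciles of input intensity the lower part, part 1, read 0.112. This decides nothing there, since input is the denominator of the ratio and on part 1 the ratio fell with input, so that matching raised the contrast from 0.057. On part 2 the ratio rose with input, and matching lowered the contrast from 0.1535 to 0.125 ± 0.0087 (SE over regions). That value stayed above 0.03 by more than 2 SE, but rests on 1 array. Whether AGO binding differs there between the states stays open, because the ChIP channel alone had a contrast of 0.264 in senescent against 0.286 in pre-senescent cells on part 1 but of 0.323 against 0.258 on part 2, and start sites were not placed.

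The low correlation of region means between the states was weighed last. Corrected for the odd and even reliability of probes, the higher of the 2 parts reached only 0.201, under the preset bound of 0.5. Noise that differs between neighbouring probes was thus argued against as the whole cause. Error shared by the probes of a region counts as reliability here, so it stays open. Among the regions brightest in the ChIP channel in both states (upper 20% of each) the higher correlation was 0.0448, which decides nothing about weak ChIP signal, since that channel is part of the ratio. A difference between cultures, hybridisations or states cannot be separated with 1 array each, and was not tested.

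The following results are given as values. In pre-senescent cells, enriched regions exceeded mirror regions by 2000 on part 1 while the difference on part 2 was −6, which is no excess either way, and the difference between the parts was not tested. In senescent cells the rank correlation of region mean with input intensity was −0.20 on part 1 and 0.41 on part 2, in opposite directions, and the difference was not tested. The random-sequence probes, used elsewhere as a background level and to compare the parts, had log2 ratios above the median of the tiled probes. The excess was 0.13 and 0.20 in pre-senescent parts 1 and 2, and 0.71 and 0.24 in senescent parts 1 and 2.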

How the results depend on the processing

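The alternatives with a threshold of 2, window span, ChIP detection, autosomes and the ChIP channel alone, and all settings of the flank contrast, were chosen after seeing the data. With the parts pooled, gained regions outnumbered lost ones in each setting run. Loess gave 5410 enriched pre-senescent and 4203 lost regions. Windows of 3 probes gave 13382 and 11057, and windows of 7 probes 5441 and 4040. A threshold of 0.75 gave 10262 lost regions. A threshold of 1.5 gave 2878 enriched pre-senescent, 8480 enriched senescent, 6867 gained and 2246 lost regions, and a threshold of 2 gave 758, 4594, 3503 and 575. The counts fall with the threshold and the window length by construction, and why loess shifted them was not tested. The correlation of region means on part 1 was 0.1244 with loess, 0.1669 with normexp, 0.1355 without the dimmest probes and −0.0284 with region medians. On part 2 it was 0.1228 with loess and 0.2584 with medians. The overlap over that of independent lists was 1.456 in the top 5%, with no allowance for the number of probes per region. The flank contrast was 0.079 with normexp and 0.0892 without the dimmest probes on part 1, and 0.0663 with loess and 0.1193 with normexp on part 2. For these the cause was not tested. The gene lists, genes per region, start-site profile and HRAS input check were not run, as no HG18 annotation was used here. No paired analysis was possible because each state had 1 array per part and no test was run. ChIP signal over the random-sequence probes was lowest on senescent part 1, at 1.47 times, which limits what can be read there.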

Other observations

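On autosomes, the ratio of AGO ChIP to input followed the density of tiled promoters differently by state and part. On part 2, senescent region means rose from 0.130 in the 20% of regions with the fewest neighbours within 500 kb to 0.337 in the 20% with the most, and pre-senescent means from −0.068 to 0.038. On part 1, pre-senescent means rose from −0.036 to 0.190, while senescent means were 0.044 and 0.027. Mean log2 input intensity of pre-senescent cells rose between the same groups of regions as well. It went from 10.2 to 10.8 on part 1 and from 9.98 to 10.6 on part 2. The ratio of single probes had a rank correlation with intensity of 0.37 and 0.21 in pre-senescent parts 1 and 2. In senescent parts 1 and 2 it was −0.02 and 0.44. The trend with density was not separated from this trend with intensity.

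Among autosomes wholly on part 2, the share of gained regions ran from 50.0% on chromosome 18 to 66.2% on chromosome 17. Neighbouring regions within 10 kb had pre-senescent means that correlated at r = 0.306 on part 1 and 0.138 on part 2, and senescent means that correlated at 0.139 and 0.251. Ratios of random-sequence probes, which both parts carry, correlated between the parts with Pearson's r = 0.66 (Spearman's rho 0.39) in pre-senescent cells and r = 0.33 (rho 0.043) in senescent cells.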
